A study of Caenorhabditis elegans with 2 samples.

How the data were processed

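Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Caenorhabditis elegans young adults 64 hours old, per the labels. The worms were of strain RW12264, in which CRISPR had been used to add a TY1, EGFP and 3xFLAG tag to the gene Y53G8AR.9 on chromosome III, and they had been synchronised by starving larvae hatched from bleached adults. Chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against GFP, per the labels. The series holds 1 group with 2 biological replicates, so no comparison between conditions exists and none was made. The labels name a possible control experiment, which was not analysed here.

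The deposited values are peak lists on the ce11 assembly, and 8 of them were used. Per the deposited text descriptions, the lists of both replicates together and of each replicate were derived from filtered alignments and a control alignment, and the thresholded lists also from a further input whose content is not described. The aligner, the peak caller and their versions are not given in the sources used here. The signal of each peak is the value the authors' peak caller gave, whose scale and correction for depth or control are not stated. The score is the authors' irreproducible discovery rate (IDR, a measure of how consistently a peak ranks in a pair of data sets) on an integer scale, and the ranked lists also hold the IDR as the authors' −log10 values. The lowest score in the deposited thresholded lists, 830, corresponds to an IDR of 0.0100. The series-wide list called conservative, thresholded on the comparison of the biological replicates, was the main peak set, and the other series-wide thresholded list was an alternative. Replicate values are the signals that the deposited lists of each replicate give for the overlapping peak with the highest signal. The ranked list for the replicate comparison also carries a pair of matched signals for each region without naming the replicates. These were used only for a correlation that does not depend on which is which. No read counts were used, so the depth of each library is unknown and no interval that needs it is given. Signals describe and rank peaks within a list, and ranks in lists of different length show no change between them.

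Peaks were placed on the WBcel235 reference (the Ensembl name of ce11) and its gene annotation, which holds 19973 protein-coding genes with 29304 distinct coding transcript starts. Every deposited peak ended within the length of its chromosome. Coordinates are 1-based. Each summit was assigned to a single class, in the order promoter (within 500 bp of a protein-coding transcript start, on either side), 5′ UTR, coding sequence, 3′ UTR, intron, noncoding gene and intergenic. A target gene is a protein-coding gene with a summit within 500 bp of a transcript start. Shares of summits were tested against 100000 circular shifts of the summits along their own chromosomes, two-sided. The smallest two-sided p this can give is 2e-05, and the smallest one-sided p is 1e-05. The same shifts were used for the number of genes of each noncoding class near a summit and, one-sided, for the overlap of the replicates' lists by at least 1 bp. Chromosome counts were compared with chromosome length, and counts in the central 33.3% of each chromosome with that share, by exact binomial tests, two-sided. The 36 fixed gene lists were tested against all other protein-coding genes by Fisher's exact test, two-sided, and 542 of the 550 gene names written in them were found in the annotation. Sequence motifs and all 6-mers and 8-mers, with reverse complements merged, were sought within 50 bp of the summit and in flanking windows of the same total width centred 300 bp to each side. An exact sign test, two-sided, compared the peaks with a match at the summit alone and in the flanks alone. In the alternatives, a flank count of 0 was taken as 1 for the ratio. GC content was compared between the same windows by sign-flip permutation, and median signals and replicate correlations by permutation, each two-sided with 100000 draws. Adjusted p values are Benjamini-Hochberg values over the 7 gene features, 6 chromosomes, 36 lists, 10 noncoding biotypes, 34 motifs, or all k-mers of a length, and the threshold was 0.05. Intervals of shares are exact 95% Clopper-Pearson intervals, which treat peaks or genes as independent and cover counting error only. The reference lists, motifs, windows, most tests and most alternatives were fixed before the data were examined. The exact binomial test of the side of the nearest start was not among them.

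The fixed lists covered ribosomal proteins, translation factors, tRNA synthetases, mitochondrial ribosome, respiratory chain, glycolysis and TCA cycle, proteasome, V-ATPase, chaperones, secretory pathway, ubiquitin system, autophagy, splicing, RNA polymerase II and Mediator, chromatin regulators, histones, cell cycle, meiosis, germ-line RNA regulators, small RNA pathways, sperm, cytoskeleton, muscle, neuropeptides, synapse, chemoreceptors, collagens and other epidermal genes, intestine, detoxification, C-type lectins and lysozymes, F-box proteins, nuclear hormone receptors, homeobox and other transcription factors, and insulin and TOR signalling. By a rule also fixed before the data were examined, the text names the tagged gene, the 20 protein-coding genes with the strongest promoter peak found in both replicates' lists, up to 4 members of each list that passed and up to 2 of 5 others, the 5 strongest peaks farther than 500 bp from coding starts, up to 3 genes of each noncoding class that passed, the motifs that passed and the 5 best k-mers of each length. Among the 20 genes, each peak counts for the gene with the nearest start alone, and ties name both. Further sequences taken from the same ranking are named as such.

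The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. The tests of promoter share, chromosomes, gene lists, noncoding classes, replicate overlap and correlation, motifs, k-mers, GC content and promoter signal were tested on simulated data, and the others were not. With 2742 random positions, the promoter test gave p under 0.05 in 2 of 100 simulations, and in 100 of 100 when 10% of the positions were placed near coding starts. Among 3600 list tests on random target genes drawn from 19973, 3 passed, and a list with 5 times the usual chance of being a target passed in 98 of 100 simulations. Unrelated lists of 1300 positions gave an overlap p under 0.05 in 5 of 100 simulations, and 100 shared positions were detected in 100 of 100. Of 657920 tests of 8-mers at random positions, 0 passed, and an 8-mer written in at 100 of 2742 summits ranked highest in 20 of 20 simulations. The GC test gave p under 0.05 in 2 of 20 simulations of random positions. The simulations drew random positions and genes independently, so they do not measure error rates under the dependence among neighbouring peaks and clustered genes.

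The alternatives were the other series-wide thresholded list, each replicate's own thresholded list, the upper 50% of conservative peaks by signal, windows of 250 and 1000 bp, random placement within 5 kb of genes, 1 transcript per gene, an expectation from coding gene numbers, assignment to the nearest start, a pair of other gene backgrounds, wider motif windows, promoter or other peaks alone, a flank 500 bp away, other overlap rules, and correlations without the top 5% of peaks or over all ranked regions. Merging overlapping peaks, restoring peaks absent from the conservative list, leaving out peaks just past gene ends, and circular shifts for the gene lists were added after the data had been seen. The text descriptions deposited with the lists were read for provenance only.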

Results

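The data are ChIP-seq peak lists for Y53G8AR.9, a C. elegans gene whose annotated product is a C3H1-type (CCCH zinc finger) domain-containing protein, tagged with EGFP at its own locus and precipitated from whole young adults with an antibody against GFP. There were 2 biological replicates of 1 group. The question such an experiment addresses is where in the genome the tagged protein is found. The files give peaks and the authors' signal values but no read counts, so the depth of each library is unknown. Signals below are the authors' own peak values, in arbitrary units, for both replicates together unless a replicate is named.

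The conservative list held 2742 peaks, which merged into 2540 separate regions and covered 841 kb before merging. Most peaks (85.7%) were 320 bp wide. Their signal ranged from 2.09 to 883 with a median of 70.4. The strongest peak, at III:3867437-3867710 (ce11), lay 280 bp from the start of rpl-3, which encodes a protein of the large ribosomal subunit. Replicate 1 alone gave 1393 thresholded peaks and replicate 2 gave 1276. Of the conservative peaks, 798 (29.1%) overlapped a thresholded peak of each replicate, 782 (28.5%) of a single replicate and 1162 (42.4%) of neither.

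The replicates shared many of their strongest regions, among them the promoters of rpl-3, rpl-35, rpl-15 and the protein-unfolding ATPase gene cdc-48.1. At rpl-3 the signal was 496 in replicate 1 and 397 in replicate 2, and at cdc-48.1 it was 269 and 264. Of replicate 1's 1393 peaks, 794 (exact 95% interval of the share 54.4% to 59.6%) overlapped a peak of replicate 2, against a mean of 0.626% in circular shifts (permutation p = 1e-05, one-sided, the smallest the shifts can give). In the other direction 783 of 1276 (61.4%, interval 58.6% to 64.0%) overlapped, against 0.675% (permutation p = 1e-05, one-sided). Across 769 pairs of overlapping peaks, log2 signals correlated with a Pearson r of 0.77 and a Spearman rho of 0.725 (permutation p = 1e-05 for each of the 2 coefficients, two-sided, adjusted p unchanged because both are equal). These are correlations across peaks, which are not independent replicates. Over all 87350 ranked regions, most of them under the threshold, rho was 0.324.

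**Figure D1:**
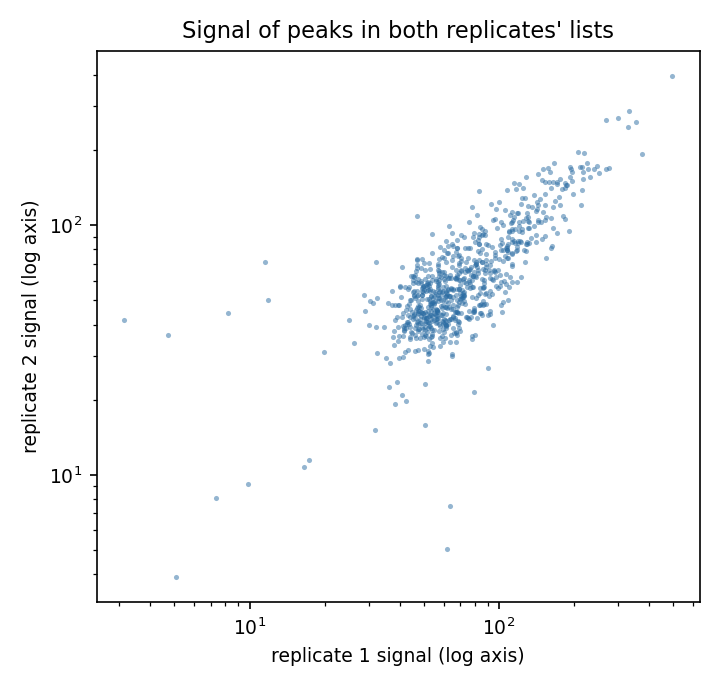
Signal of the 769 peaks present in both replicates' thresholded lists, replicate 1 on the horizontal and replicate 2 on the vertical log axis, in the authors' signal units, with 1 point per pair of overlapping peaks. The points rise together, with a Spearman rho of 0.725.

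Summits gathered at the starts of protein-coding genes, mostly just upstream. For the 20 genes with the strongest such peaks, each peak was counted for the gene with the nearest start alone. Other genes sharing a peak, such as rpl-20, are therefore not among the 20. The 20 included the ribosomal protein genes rpl-3 (signal 883), rpl-35 (616), rpl-15 (607), rps-1 (396), rpl-12 (368) and rpl-7A (351). Genes for mitochondrial proteins were Y17G9B.5 (555), whose product is a mitochondrial ECSIT-like protein, the cytochrome c oxidase subunit gene cox-5A (403) and the import factor gene ddp-1 (345). Genes of protein turnover and maturation were cdc-48.1 (542), the ubiquitin ligase genes eel-1 (403) and wwp-1 (391), the TASPase homologue tasp-1 (582) and the thioredoxin-domain gene Y55F3AR.2 (417). Genes of RNA handling and translation were drr-2 (408), which encodes an RNA-binding protein, the splicing helicase gene mog-4 (395), the CCR4-NOT subunit gene ntl-11 (337) and the initiation factor gene eif-3.C (336). The remaining 2 were K08F11.1 (580) and Y39B6A.43 (375).

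Of the 2742 summits, 1224 (44.6%, interval 42.8% to 46.5%) lay within 500 bp of a coding transcript start, against 23.1% in circular shifts (SD 0.899 over shifts), a ratio of 1.93 (permutation p = 2e-05, two-sided, the smallest the shifts can give). Of these 1224, 827 (67.6%) were upstream of the nearest start (exact binomial p = 2.86e-35, two-sided), with a median position of -103.5 bp. Not all of the 1224 were clear of gene ends: 838 lay outside the 300 bp past the end of any coding gene. That zone was chosen after the results were seen and is described under other observations. A gene end can lie just upstream of the next start, and the share upstream was not computed for the 838 alone. The test of side also treats overlapping peaks as independent. Starts of a pair of genes on opposite strands were often both close to the summit: 201 summits (7.33%, interval 6.38% to 8.37%) had starts on opposite strands within 500 bp, against 1.06% in shifts, a ratio of 6.91 (permutation p = 2e-05, two-sided). One such peak, at IV:13240583-13240787, lay 31 bp from the start of rpl-12 and 362 bp from that of lin-54, and another, at IV:1094253-1094462, served as the promoter peak of both Y55F3AR.2 and the chaperonin subunit gene cct-8.

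Fewer summits than in shifts lay in coding sequence and introns, and more in 3′ UTRs. Each summit has a single class and promoters come first, so the promoter excess lowers the shares left for the other classes. Among summits outside promoters, coding sequence and introns still held smaller parts than in shifts, a comparison that was not tested. Coding sequence held 303 summits (11.1%, ratio 0.613 to shifts) and introns 351 (12.8% against 27.1%, ratio 0.472). The 3′ UTR class held 147 (5.36% against 2.65%, ratio 2.02). Each of these classes had an adjusted permutation p of 3.5e-05, two-sided. Intergenic sequence away from starts held 600 summits (21.9% against 25.2%, adjusted permutation p = 0.00179, two-sided). It did not pass in either replicate's own list, in the upper 50% of peaks or with the absent peaks restored. This deficit goes with the promoter excess: among the 1518 summits outside promoters, the intergenic part was larger than in shifts, which was not tested. The 5′ UTR class beyond 500 bp of starts (6 summits, adjusted permutation p = 0.669) and noncoding genes (111 summits, adjusted permutation p = 0.424) did not pass. The median signal was 74.1 at promoters and 68.5 elsewhere, a difference of 5.58 (permutation p = 1e-05, two-sided) that was small beside the quartiles of 58.9 and 106 at promoters and 55.2 and 90.7 elsewhere.

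**Figure D2:**
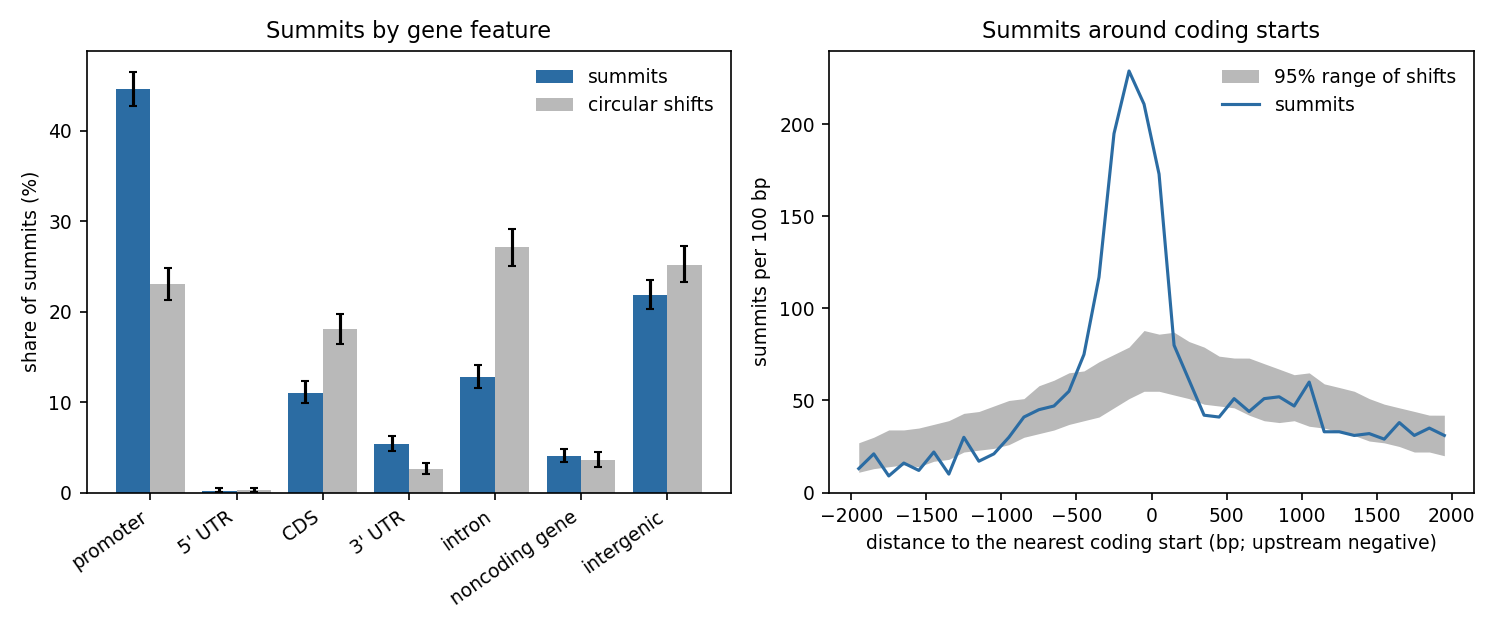
Left, percent of the 2742 summits in each gene feature (blue, with exact 95% intervals) and in circular shifts (grey, with the central 95% of shifts). Right, summits per 100 bp by signed distance in bp to the nearest coding start, with the central 95% of a smaller set of shifts in grey. The summits peak just upstream of the start.

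The strongest peaks farther than 500 bp from any coding start were at X:11094044-11094345 (signal 467, intergenic, 1472 bp from the nearest annotated gene, a tRNA gene), I:4769529-4769769 (437, intergenic, 581 bp from the lincRNA gene M04F3.7), II:4047952-4048180 (416, intergenic, 457 bp from a pseudogene), III:835765-836187 (386, in the coding sequence of dos-3) and IV:4727942-4728139 (379, intergenic, 85 bp from a pseudogene). All 5 overlapped thresholded peaks of both replicates.

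Peaks were denser on chromosomes I and III and sparser on V and X. Chromosome III carried 497 summits (36.1 per Mb, ratio 1.32 to its share of the genome, adjusted exact binomial p = 4.89e-10, two-sided) and chromosome I carried 516 (34.2 per Mb, ratio 1.25, adjusted exact binomial p = 1.5e-07). Chromosome V, which holds most of the large chemoreceptor families, carried 474 (22.7 per Mb, ratio 0.828, adjusted exact binomial p = 3.85e-06) and X carried 348 (19.6 per Mb, against 29.0 per Mb on the autosomes; ratio 0.718, adjusted exact binomial p = 7.47e-12). Chromosomes II (434) and IV (473) did not pass (adjusted p = 0.474 and 0.801 in the same exact binomial tests). On the autosomes, whose central parts hold many conserved genes, 995 of 2394 summits (41.6%, interval 39.6% to 43.6%) lay in the central 33.3% of the length (exact binomial p = 4.89e-17, two-sided). On X the share was 33.3% of 348 summits (exact binomial p = 1). With coding gene numbers in place of length as the expectation, I, III and V still passed and X did not (adjusted exact binomial p = 0.169), and V did not pass in replicate 2's own list (adjusted exact binomial p = 0.17). Overlapping and neighbouring peaks are not independent, so these p values are smaller than independent peaks would give.

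Genes of the ribosome, energy metabolism and protein folding were the targets most often. Of 81 cytosolic ribosomal protein genes, 48 (59.3%) had a summit within 500 bp of a start, among them rpl-3, rpl-35, rpl-15 and rpl-20 (signal 555, a peak shared with Y17G9B.5), against 6.29% of other coding genes (odds ratio 21.7, adjusted Fisher p = 1.13e-34). The secretory pathway and unfolded protein response list had 17 of 40, led by cdc-48.1, the translocon genes trap-3 (257) and sec-61.G (256) and the ER chaperone gene hsp-3 (183) (odds ratio 10.8, adjusted Fisher p = 1.53e-09). Chaperonin and heat shock genes had 18 of 58, with cct-8 (417), the J-domain genes dnj-13 (286) and dnj-9 (282), and hsp-1 (244), an HSP70 gene (odds ratio 6.55, adjusted Fisher p = 1.29e-07). The respiratory chain and ATP synthase had 16 of 50, with cox-5A, atp-1 (300), cox-5B (255) and cox-6B (173) (odds ratio 6.84, adjusted Fisher p = 4.02e-07). Glycolysis, gluconeogenesis and the TCA cycle had 14 of 45, with pck-2 (218), gpi-1 (143), icl-1 (128) and aldo-2 (120) (odds ratio 6.55, adjusted Fisher p = 3.35e-06). The V-ATPase had 8 of 21, including vha-8 (109) and vha-2 (107) (odds ratio 8.90, adjusted Fisher p = 9.71e-05). The secretory, chaperonin and V-ATPase lists did not pass when only genes of the autosomal centres were compared. That comparison keeps only list members lying in the centres, which lowers its power. The losses there therefore do not show that chromosome position accounts for these lists. The V-ATPase also did not pass in the list of replicate 2 alone. The ribosome, respiratory chain and glycolysis lists passed under all alternatives.

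Further lists with more targets covered nuclear, germ-line and cytoplasmic functions. Splicing factors had 14 of 48, with rsp-2 (175) and snr-4 (159) (adjusted Fisher p = 6.91e-06), and translation factors 11 of 39, with eif-3.C, iff-2 (290) and the elongation factor genes eef-2 (258) and eef-1G (191) (adjusted Fisher p = 9.36e-05). Germ-line RNA regulators had 13 of 48, with puf-3 (117), mex-1, the yolk receptor gene rme-2 (82.5) and pos-1 (78.5) (adjusted Fisher p = 3.17e-05). Chromatin regulators had 10 of 39, led by lin-54 (368), lin-53 (312) and lin-9 (262), which encode subunits of the DREAM repressor complex (adjusted Fisher p = 0.000438). Meiotic genes had 9 of 41, including coh-3 (111) and brc-1 (106) (adjusted Fisher p = 0.00226), histones 10 of 50, including his-37 (219) (adjusted Fisher p = 0.00246), and RNA polymerase II and Mediator genes 11 of 61, including rpb-11 (253) (adjusted Fisher p = 0.0033). Replication and cell cycle genes had 9 of 47, with pcn-1 (266), which encodes the PCNA sliding clamp, and mcm-2 (170, with no overlapping peak in replicate 1) (adjusted Fisher p = 0.00525). Small RNA pathway genes had 9 of 50, led by ego-1 (279) (adjusted Fisher p = 0.00726), but passed under only 6 of 13 alternatives and in neither replicate's own list. Cytoskeletal genes had 14 of 72, with cap-2 (260), tbb-1 (257) and tba-2 (239) (adjusted Fisher p = 0.000525), autophagy and lysosome genes 13 of 70, including vps-4 (158) and lgg-2 (117) (adjusted Fisher p = 0.00116), and the proteasome 7 of 33, including rpn-3 (236) (adjusted Fisher p = 0.00726). Of these 12 lists, only splicing, translation factors and the cytoskeleton passed under all 13 alternatives. Among genes of the autosomal centres, where lists keep only their central members, 7 lists did not pass. They were the germ-line RNA, chromatin, meiosis, RNA polymerase II, cell cycle, small RNA and proteasome lists. The germ-line RNA and RNA polymerase II lists passed in neither replicate's own list, the proteasome did not in that of replicate 2, and the meiosis, cell cycle and autophagy lists did not in that of replicate 1. Histones and the cell cycle list did not pass with 250 bp, histones and the proteasome without peaks past gene ends, the cell cycle list with the nearest start only, and RNA polymerase II in the upper 50% of peaks.

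Several large gene families had fewer targets than other genes. Of 1292 chemoreceptor genes, 7 (0.542%) had a summit near a start (odds ratio 0.0733, adjusted Fisher p = 4.01e-28), the strongest being sri-5 (256) and srh-269 (213, a peak that also lay 114 bp from a tRNA gene). F-box genes had 3 of 315, led by fbxb-85 (231) (adjusted Fisher p = 1.1e-05), C-type lectins and lysozymes 6 of 319, led by spp-2 (106) (adjusted Fisher p = 0.000525), detoxification enzymes 2 of 205, gst-9 (115) and gst-27 (106) (adjusted Fisher p = 0.000652), and nuclear hormone receptors 7 of 274, led by nhr-47 (227) (adjusted Fisher p = 0.00726). Only the chemoreceptors passed under all 13 alternatives. The other 4 lists did not pass against circular shifts, which set them against moved summits rather than other genes. The F-box, lectin and nuclear hormone receptor lists did not pass among genes of the autosomal centres, where fewer members are compared. Detoxification enzymes passed in neither replicate's own list.

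In all, 1299 of 19973 protein-coding genes (6.50%) were targets, and 18 of the 36 lists had more and 5 fewer targets than other genes after adjustment over the lists, while 13 did not pass. Without adjustment, 26 lists had a Fisher p under 0.05. The lists that did not pass were neuropeptides (3 of 140, including ins-13 with 60.7, adjusted Fisher p = 0.0548), homeobox genes (1 of 85, ceh-99 with 49.8, 0.0636), sperm genes (0 of 53, 0.0672), the ubiquitin system (10 of 89, including ubc-6 with 157, 0.108), tRNA synthetases (4 of 32, including ears-2 with 130, 0.195), intestine and vitellogenins (5 of 45, including vit-2 with 121, 0.257), collagens (7 of 175, 0.257), the mitochondrial ribosome (7 of 70, 0.257), synapse (2 of 69, 0.366), other transcription factors (12 of 145, 0.431), insulin and TOR signalling (3 of 34, 0.512), other epidermal genes (1 of 33, 0.743) and muscle (3 of 51, 1). Fisher tests treat genes as independent, and family members in clusters are not. Against genes of the autosomal centres alone, 8 lists stood higher and 2 lower. Against circular shifts 22 stood higher and 1, the chemoreceptors, lower. The shifts set a list against moved summits rather than other genes, so a list with an average share of targets can stand higher there.

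**Figure D3:**
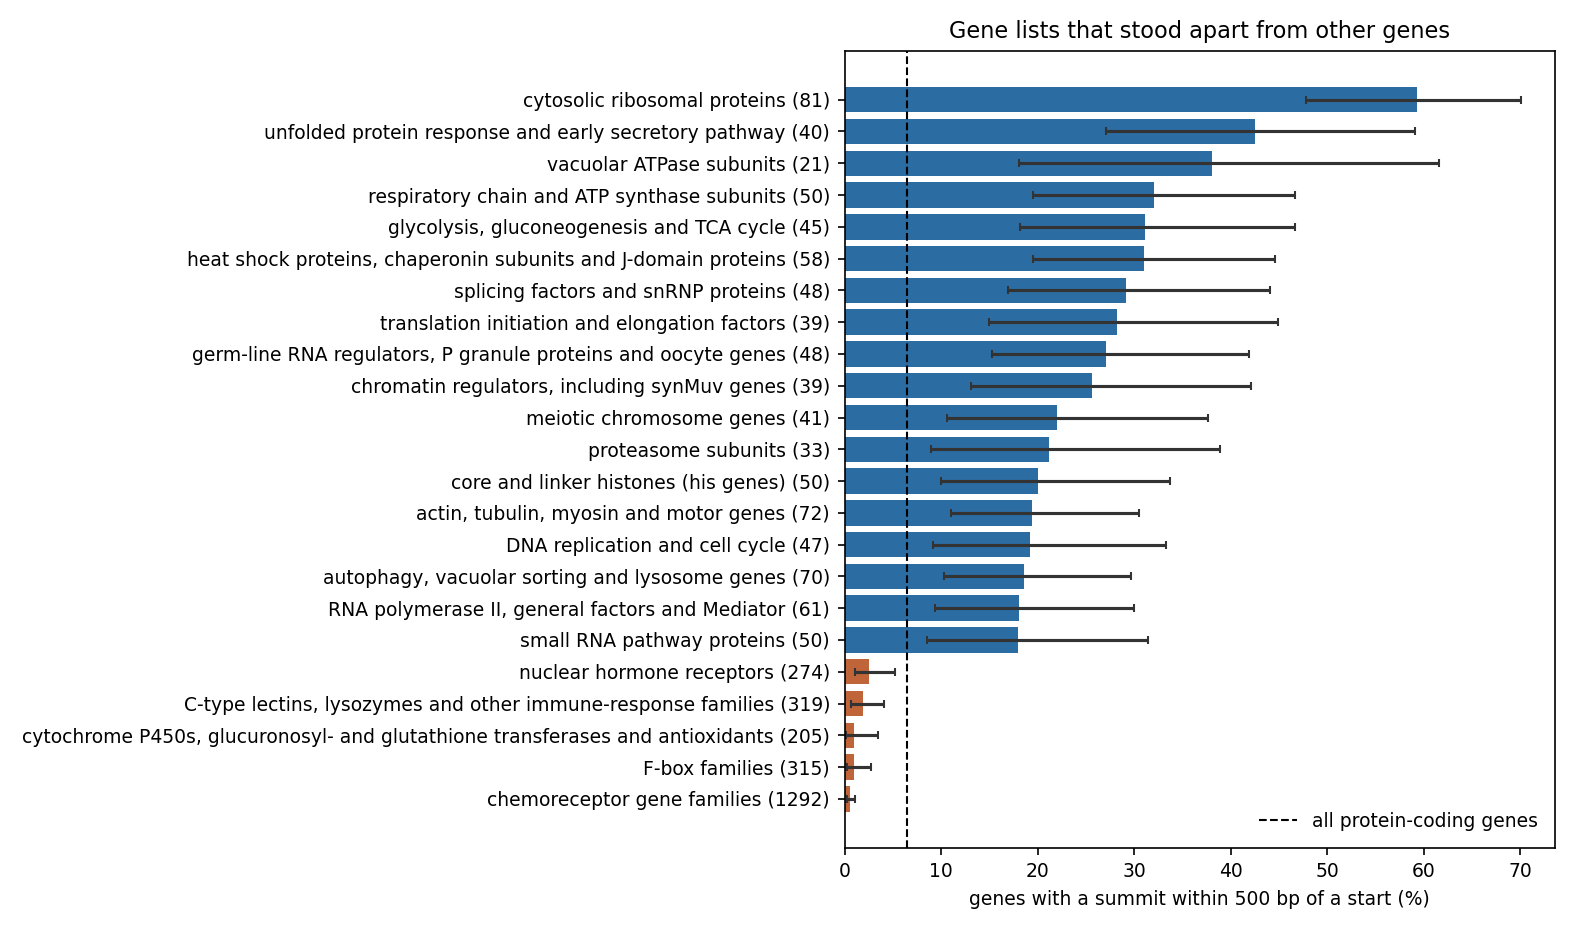
Percent of genes in each fixed list with a summit within 500 bp of a transcript start, for the 23 lists that passed, with exact 95% intervals and the number of genes in brackets; blue lists were higher and orange lists lower than other genes. The dashed line marks all protein-coding genes (6.50%).

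Genes for tRNAs and for small nuclear and nucleolar RNAs were often beside summits. Of 612 tRNA genes, 169 (27.6%) had a summit within 500 bp, a ratio of 12.2 to circular shifts, with the strongest at X:8036297-8036542 (signal 215). Of 129 snRNA genes 37 did (28.7%, ratio 11.6), led by the spliced leader RNA genes sls-2.1 (329), sls-2.4 (320) and sls-2.2 (207), and 99 snoRNA genes did (28.6%, ratio 11.0), including ZK994.7 (354) in an intron of pxn-1 and Y24D9A.9 (351), which shares its peak with rpl-7A. The annotation's general ncRNA class had 437 of 7764 (ratio 2.43), with the strongest peaks shared with K08F11.1, Y55F3AR.2 and rps-1. Each of these 4 classes had an adjusted permutation p of 5e-05, two-sided. The shifts set the classes against random placement, and the share of the general ncRNA class (5.63%) was below that of coding genes (6.50%). Repeated sequence and neighbouring coding starts were examined for the tRNA genes alone, not for the snRNA and snoRNA genes. MicroRNA genes had 22 of 261 (8.43%, interval 5.36% to 12.5%, ratio 3.33, adjusted permutation p = 0.000467), including mir-45 (136), mir-80 (115) and mir-5549 (110). That interval holds the 6.50% of coding genes. piRNA genes had 66 of 15363 (ratio 0.174, adjusted permutation p = 8e-05), the strongest being 21ur-12279, whose peak was that of atp-1, and pseudogenes 31 of 2128 (ratio 0.614, adjusted permutation p = 0.0109). Antisense RNAs (4 of 100, adjusted permutation p = 0.591), lincRNAs (4 of 194, adjusted permutation p = 1) and rRNA genes (0 of 20, interval up to 16.8%, adjusted permutation p = 1) did not pass. A ranked peak with a signal of 222 that the conservative list lacks, chosen after its values were seen, lay 134 bp from the rRNA gene rrn-4.2. The pseudogenes did not pass with 250 bp or in replicate 1's own list. Nearly all tRNA genes hold sequence that is repeated in the genome: 590 of the 612 did, and among the other 22 only 2 had a summit.

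**Figure D4:**
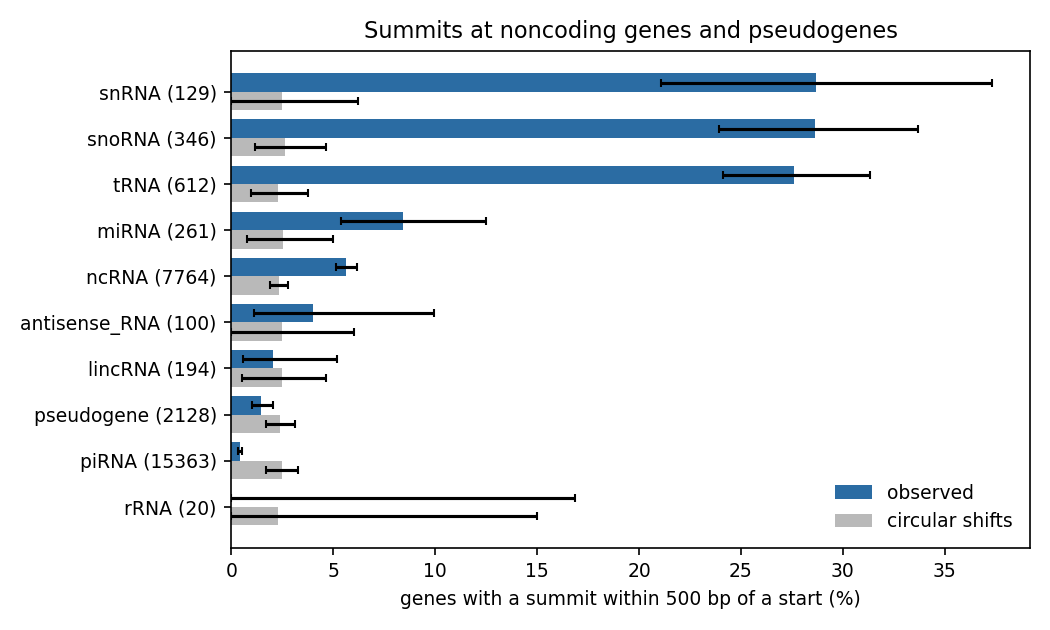
Percent of genes of each noncoding biotype and of pseudogenes with a summit within 500 bp of a start (blue, exact 95% intervals) and in circular shifts (grey, central 95% of shifts), with the number of genes in brackets. The snRNA, snoRNA and tRNA classes all stand above 27%.

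The sequence at summits was rich in CG-containing words and poor in A and T runs. CTGCGTCT, an 8-mer in the fixed list, was found within 50 bp of 130 summits and in 14 flanks (calls below rest on exact sign tests adjusted over 34 motifs). The CGCGCG repeat was found at 121 summits and 21 flanks, the E2F-type site TTSSCGC at 252 and 100, and the RNA polymerase III B box GGTTCGANTCC at 34 and 1. Smaller excesses were seen for the THAP core (107 and 43), the GC box (115 and 49), the E-box CACGTG (3.79% of summits and 1.75% of flanks), GA repeats (87 and 38), the KLF site (73 and 38), the E-box CAGCTG (83 and 48), the heat shock element (42 and 23), the CREB site (28 and 11) and CCGCGAG (31 and 15). The TATA box (6.24% of summits and 12.6% of flanks), the start codon context (535 summits and 744 flanks), the splice acceptor TTTCAG (352 and 533), T blocks (88 and 189), the GATA site (419 and 602) and the homeodomain site (60 and 143) were scarcer at summits, as were, by less, the PHA-4 site (693 and 798), the SKN-1 core (840 and 930) and the nuclear receptor site TGAACT (136 and 178), whose ratio was 1.14 in replicate 2's own list. In all, 13 of 34 motifs were higher and 9 lower, and 12 others did not pass. GC content at summits was on average 8.63 points above that of the flanks. The motif tests matched neither base composition nor position relative to gene starts. Excesses and deficits of single motifs can therefore reflect these differences rather than a preference for the site. Composition was examined only for AGACGCAG, the reverse complement of CTGCGTCT. The 8-mers of its composition had a median ratio of 1.5, with 1 added to each count. The exact sign test p was 3.46e-25 for CTGCGTCT, 6.94e-19 for CGCGCG, 4.02e-17 for TTSSCGC, 4.98e-16 for the TATA box and 2.1e-09 for the B box, two-sided and before adjustment. Only 6 motifs were higher among promoter peaks alone, 7 to 8 in the replicates' own lists, and 8 with windows of 100 bp. CTGCGTCT, CGCGCG, the E2F-type site and the GC box, and the first 6 of the scarcer motifs, passed in promoter peaks and in both replicates' lists. Among promoter peaks the B box, CACGTG, GA repeats, the KLF site, the heat shock element, the CREB site, CCGCGAG and the last 3 scarcer motifs did not pass. The KLF site, CAGCTG, the CREB site, CCGCGAG, the PHA-4 site and TGAACT passed in neither replicate's list, the THAP core not in that of replicate 2, and GA repeats and the heat shock element not in that of replicate 1.

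A search without a prior list gave 606 higher and 331 lower of 2080 6-mers, and 386 higher and somewhat fewer lower of 32896 8-mers. In the replicates' own lists, which hold fewer peaks, 351 to 374 6-mers were higher and 216 to 252 lower, and 110 to 124 8-mers were higher and 55 to 82 lower. The 5 best 6-mers were all scarcer at summits: TTAAAA (358 summits and 781 flanks), TAAAAA, AAAAAT, AAAATT and AAAAAA. The best 8-mers were AGACGCAG, the reverse complement of CTGCGTCT, GAGACGCA (126 and 12), AAACGCGC (77 and 2), GACGCAGA (4.08% of summits and 0.511% of flanks) and, scarcer, AAAAAAAA (149 and 338). The best-placed richer 6-mer was ACGCGC (219 and 31). Chosen on the peaks of even rank, AGACGCAG was again richer at the 1371 summits of odd rank, with 63 summits and 9 flanks (exact sign test p = 1.83e-11, two-sided). Chosen on odd ranks, TTAAAAAA was scarcer at the others (43 summits, exact sign test p = 2.19e-07, two-sided). The GC content was 44.6% within 50 bp of summits, on average 8.63 points above that of the flanks (SD 11.6 over 2742 peaks, permutation p = 1e-05, two-sided). Of the 559 8-mers with the base composition of AGACGCAG, 6 had a ratio of summits to flanks as high. With 1 added to each count, the ratio of AGACGCAG was 8.73 and the median over the 559 was 1.5. The 6 include GAGACGCA, which overlaps AGACGCAG, so they are not all separate words.

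**Figure D5:**
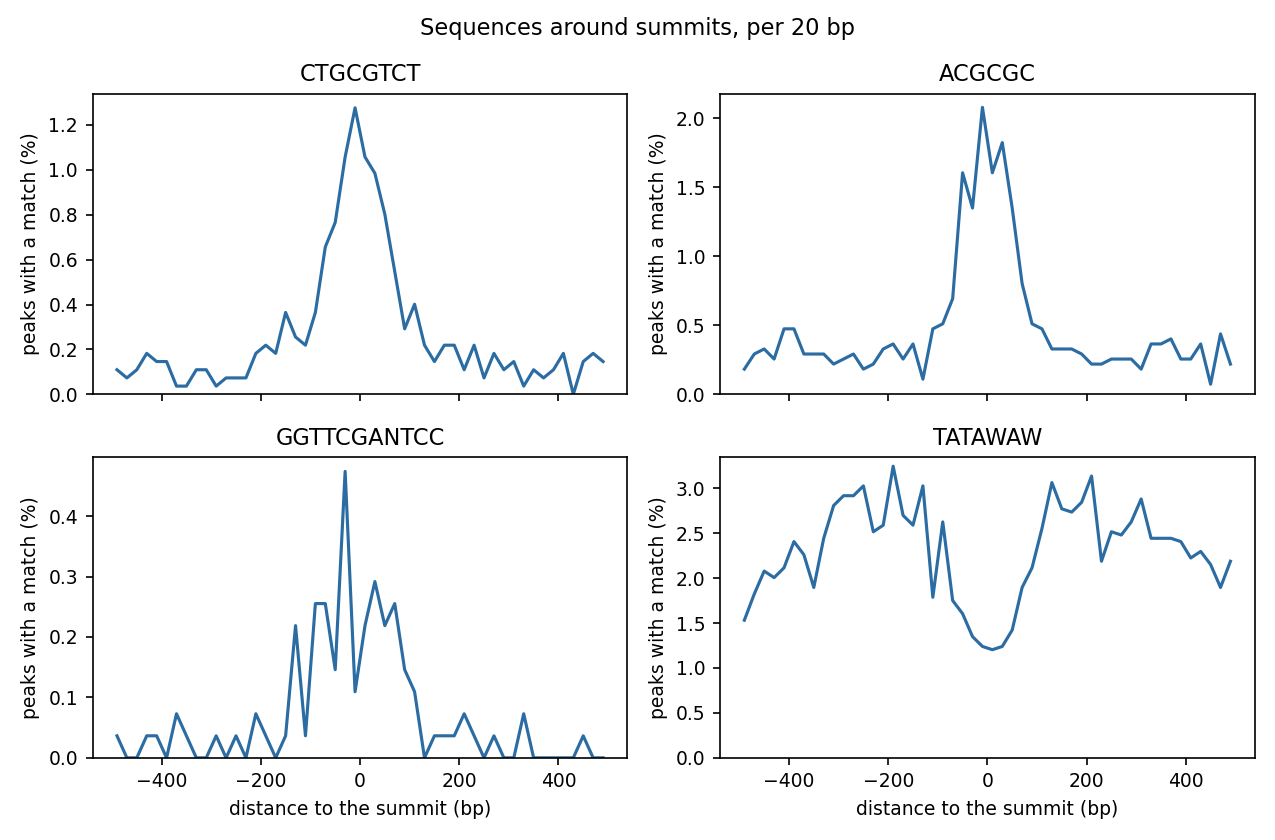
Percent of the 2742 peaks with a match to each of 4 sequences per 20 bp, by distance from the summit in bp. CTGCGTCT, ACGCGC and the B box GGTTCGANTCC peak near the summit and the TATA box dips there.

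The tagged gene itself had no thresholded peak. Y53G8AR.9 lies at III:3317725-3321245 on the minus strand, and 0 peaks of the conservative list, the other series-wide thresholded list or either replicate's thresholded list had a summit within 500 bp of it. The nearest conservative summit was 68396 bp away. The ranked lists, which include peaks under the threshold, held 8 peaks at the gene, the best at III:3317492-3317811 with a signal of 51.2 (rank 3655 of 87350 and IDR 0.0209 in the replicate comparison, IDR 0.633 in the other series-wide ranked list) and a summit 73 bp beyond the 3′ end. The best peaks at the gene in the replicates' own ranked lists had an IDR of 0.0721 and 0.103.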

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

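The pattern in this part was noticed in the data, and its tests were written down before their results were seen. A set of high-scoring peaks sat in the ranked list but not in the conservative list. The ranked list for the replicate comparison held 2866 peaks at or above the lowest score of the conservative list, and the conservative list lacked 124 of them (4.33%), including 6 of the 20 strongest. The strongest, at X:15810951-15811203 (ce11), had a signal of 2107, 2.38 times that of the strongest conservative peak, and lay 859 bp from a pseudogene. These peaks stand out because the score alone would have kept them. Not all had a strong signal: their median was 87.3, against 70.4 for conservative peaks, and the lowest was 8.29.

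Repeated sequence and a fixed removal of regions both met their tests. Within 100 bp of the absent summits, a median of 92.6% of 32-base words occurred more than once in the genome, against 0% at conservative summits (permutation p = 1e-05, two-sided), and 89.5% of the absent peaks against 4.08% of conservative peaks were repeated over more than 50% of that window. High-scoring peaks missing from each replicate's own thresholded list lay within 1000 bp of these same places in 94.4% (replicate 1) and 92.8% (replicate 2) of cases. Of the retained peaks, 3 of 1393 and 1 of 1276 did. The values are consistent with the removal of a fixed set of repeat-rich regions from every list, as the undescribed input to the thresholded lists could do, and the signal there may come partly from reads shared between copies. Whether the tagged protein is also present at these repeats stays open, and no biological explanation was tested, since the design has 1 group.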

How the results depend on the processing

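Merging overlapping peaks, restoring the absent peaks, leaving out peaks past gene ends and circular shifts for the lists were chosen after the data had been seen. Of 163 values of the comparisons under the alternatives, 138 kept their direction and side of the threshold or stayed within 1.5 times the reported count. The shares at promoters (30% with 250 bp to 61.6% with 1000 bp), opposite-strand starts, autosomal centres and gene ends, the GC difference, the promoter signal difference and both replicate comparisons passed under every alternative run for them. Among single features, chromosomes, lists, biotypes, motifs and k-mers that passed, 630 of 723 values also passed in the same direction, 92 fell short of the threshold and 1 reversed: the nuclear receptor site TGAACT had a ratio of 1.14 without replicate 1, and 0.918 without replicate 2. With the replicates' own lists, which hold fewer peaks, the peak count was 1276 to 1393, the motifs higher at summits 7 to 8, the higher 8-mers 110 to 124, the lower 8-mers 55 to 82, the higher 6-mers 351 to 374 and the lower 6-mers 216 to 252. In the upper 50% of peaks by signal, which has 1371 peaks, 197 8-mers were higher and 150 lower. Fewer peaks lower the power of these tests by construction. With windows of 100 bp, 8 motifs were higher and 172 8-mers lower, and among promoter peaks 6 motifs were higher. Among autosomal central genes 8 lists were higher and 2 lower, against genes with 3- or 4-letter names 8 were lower, and with circular shifts 1 was lower. The comparison among central genes keeps only the list members lying there, which also lowers power by construction. Circular shifts set a list against moved summits rather than other genes, and summits as a whole lay near starts 1.93 times as often as in shifts. A list with an average share of targets can therefore stand higher there, and a list with fewer targets need not stand lower. The cause was not tested further for the wider windows, the central genes or the named genes. The lists of ribosomal proteins, translation factors, the respiratory chain, splicing, cytoskeleton, glycolysis and chemoreceptors passed under all 13 alternatives run for each, and that of small RNA pathways under 6. At the tagged gene, each series-wide ranked list held 8 peaks and each replicate's ranked list held 4, because ranked lists include peaks under the threshold. Depth is unknown, so its part in the limits of these lists could not be measured.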

Other observations

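The zone just past gene ends, its gene lists, the first test below (peaks far from coding starts) and the tRNA test on summits in unique sequence were chosen only after the results were seen. Many summits stood just downstream of protein-coding genes. Of 2742 summits, 884 (32.2%, interval 30.5% to 34.0%) lay 0 to 300 bp past the annotated end of a coding gene, against 5.78% in circular shifts, a ratio of 5.58 (permutation p = 2e-05, two-sided, the smallest the shifts can give). The last 300 bp inside genes held 12.1%, against 5.89% in shifts. The number of summits was highest 100 to 200 bp past the end, with 368 against a mean of 49.1 in a smaller set of 200 shifts. Examples, chosen after their values were seen, were the infection-response factor gene zip-2 (summit 156 bp past its end, signal 386, the peak in dos-3 named above), the intestinal neuropeptide gene nlp-40 (179 bp, 322), the convergent pair hsp-1 and nra-1 (58 and 67 bp, 249), the desaturase gene fat-6 (159 bp, 228), the vitellogenin gene vit-6 (253 bp, 217) and the tubulin gene tbb-2 (181 bp, 210).

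When peaks within 1000 bp of coding starts were set aside, 368 genes kept a peak past their end. Among them, 14 of the 36 fixed lists were higher and 1 lower. The comparison was with all other coding genes, although short genes or genes ending close to a start could hardly keep such a peak. Gene length and spacing therefore enter these list results. Germ-line RNA regulators had 11 of 48 (adjusted Fisher p = 3.16e-08), intestine and vitellogenin genes 9 of 45 (adjusted Fisher p = 1.03e-06), the proteasome 8 of 33 (adjusted Fisher p = 1.03e-06) and chemoreceptors 2 of 1292 (adjusted Fisher p = 1.98e-07). Other transcription factors had 10 of 145 (adjusted Fisher p = 0.00218) and muscle genes 4 of 51 (adjusted Fisher p = 0.0344). The intestinal, transcription factor and muscle lists had not passed for peaks at starts. These differences between the 2 positions were not themselves tested. Summits outside the zone past gene ends were still near coding starts in 45.1% of cases, against 22.6% in shifts (permutation p = 2e-05, two-sided).

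The tables argue against each of 3 simple accounts as the whole cause of the peaks past gene ends. Among 1052 peaks farther than 1000 bp from coding starts the share was 33.4% (351 summits), against 4.76% in shifts. Starts of neighbouring genes are therefore not the whole cause. The rest of the 884 summits past gene ends lay within 1000 bp of a coding start, and this test does not cover them. The share far from starts was 38.3%, against 4.90% in shifts, after peaks beside noncoding genes were also set aside, piRNA genes and pseudogenes excepted. For all 2742 peaks, of which 32.2% lay past gene ends, positions of the same GC content gave 4.89% (permutation p = 0.0002 over 10000 draws, two-sided). The authors' lists drew on a control alignment, but how it was used is not stated, and the control was not analysed here. A recovery of such DNA that does not depend on the tagged protein therefore stays open. No biological explanation was tested, the same data having given both pattern and tests.

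The peaks at tRNA genes cannot be told apart from reads shared between gene copies. Among the 22 tRNA genes with no repeated 32-base word, 9.09% had a summit (2 genes, interval 1.12% to 29.2%, permutation p = 0.189, two-sided), an interval that holds both the 2.35% of shifts and the 28.3% of the other 590 genes. With only peaks in unique sequence, 2.94% of tRNA genes had a summit, against 1.80% in shifts (permutation p = 0.106, two-sided), but that filter removes summits on the repeated genes themselves whatever their cause. Starts of neighbouring coding genes are not the whole cause, since 27.6% of the 387 tRNA genes farther than 1000 bp from them had a summit, 12.5 times the share in shifts (permutation p = 2e-05, two-sided). No biological explanation was tested for these peaks.

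A further hypothesis was that targets have the codon usage of highly expressed genes. Outside the ribosomal protein list, which served as the reference, target genes had a median codon adaptation index of 0.285 and other genes 0.250 (permutation p = 1e-05, two-sided). Of the genes in the top 10% of the index 13.6% were targets, and of those in the bottom 10% 1.27%. With chemoreceptor genes also left out the shares were 13.9% and 2.45%, so this family carried part of the contrast. The values are in line with a link to expression, but the index is no measurement of transcription in these worms. A recovery of highly transcribed chromatin in any precipitation could give the same result and was not tested.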
